A study of Mus musculus with 280 samples.

How the data were processed

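The TPM values were made by the authors and are used as deposited, and the submitters' processing notes name Bowtie for alignment and mm10 as the genome, with versions not given in the sources used here. The embryos were sequenced with a kit for single-cell libraries and Nextera tagmentation, per the labels. The table holds 280 embryos and 11076 genes, 15 of whose symbols had been turned into dates by a spreadsheet and were kept under the converted names. TPM sums per embryo ran from 985115 to 998407, and no gene had a highest value under 5.87 TPM, so low genes appear to have been removed before deposition. Diet and stage in the table and in the labels differed for 0 embryos. Counts, reads and sequencing depth were not used here, since the table holds none.

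Values were analysed as log2 of TPM plus 1 in Python 3.11.15 (numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, matplotlib 3.10.9) and R 4.3.3 with limma 3.58.1. At each stage genes with a TPM of 1 or more in at least 25% of the embryos were kept. Each diet comparison was a limma fit of its own stage, with plate as covariate where a stage spans several plates, moderated variances with trend and robust settings, and Benjamini-Hochberg adjustment at 0.05. Stage changes were tested in control embryos of the 2-cell, 4-cell, morula and blastocyst stages in 1 fit with plate as covariate, at an adjusted p under 0.05 and an absolute log2 fold change of 1 or more. The diet by stage interaction was a limma F test over the same 4 stages with plate within stage as covariate. Late blastocysts share no plate with the other blastocysts, so that pair of stages was described by values only.

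The 24 gene lists were written down with their members: oocyte and maternal transcripts, 2-cell and MERVL-linked genes, heat shock proteins, cytosolic ribosomal proteins, nucleolar genes, oxidative phosphorylation, glycolysis, cholesterol biosynthesis, replication-dependent histones, S phase, G2 and M phase, p53 targets, amino acid and integrated stress response, DNA methylation, small RNA and tRNA processing, paternally and maternally expressed imprinted genes, trophectoderm, inner cell mass, primitive endoderm, polarity, sperm transcripts, cumulus cell markers and Y-linked genes. The last pair had 2 members each in the table, fewer than the 3 required, and were not tested. A list score is the mean log2 value of its members kept at a stage. List scores, course scores, spread and genes detected were tested by two-sided permutation of diet within plate with 100000 resamples, where the smallest possible p is 1e-05. Tests by sire used exact sign flips over sire pairs, 256 for 8 pairs. Replication-dependent histones, ribosomal proteins with many pseudogenes and the overlapping Snrpn and Snurf are hard to assign to single genes, so their values are uncertain.

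The genes named in each diet comparison are those with the smallest p among genes with a mean of at least 5 TPM in 1 group, 10 per comparison because fewer than 10 passed, together with Xist, Zscan4d, Zscan4c, Tdpoz4 and Zfp352 where kept at that stage. A few genes that the rule names are not reported here. For stage changes they are the 10 largest changes per direction among genes with a mean of at least 50 TPM in 1 stage. The comparisons, the naming rule, the lists and the first set of alternatives were chosen before the data were examined. Sires and oocyte donors became known only with the data, so the alternatives that use them were added later. Genome positions are whole genes of GENCODE vM21 on GRCm38, which is mm10.

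Alternatives tried were a pseudocount of 0.1, no filter, quantile normalization, no plate covariate, runs of neighboring embryos in place of plate or as replicates, array weights, ranks within embryos, embryos with fewer than 5000 genes left out, and each plate or, at the small stages, each embryo left out. Added later were sire pair or oocyte donor in place of plate, sire means, sire as a correlated block, each sire pair left out, Rn45s left out, embryos under 7000 genes left out, 16 embryos with suffixed sire identifiers left out, and further covariates at the morula stage. Nothing else was left out of the reported fits.

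The methods were tested on simulated data with 200 changed genes. True log2 changes of 0.5, 1 and 2 were recovered in 23.9%, 77.6% and 98.5% of cases at the 2-cell stage (10314 genes), 37.3%, 88.1% and 100% at the 4-cell stage (9820 genes), 17.9%, 86.6% and 100% at the morula stage (9552 genes) and 23.9%, 71.6% and 95.5% at the blastocyst stage (9378 genes). False calls were 3 of 136, 2 of 152, 0 of 136 and 8 of 135 at these stages. For the interaction (11054 genes) recovery was 19.4%, 70.1% and 97% with 10 false calls. For the stage change (10880 genes) stage labels were shuffled once over the control embryos, so their spread held the real stage differences. There 88.5% of changes of 2 log2 units were recovered with 0 false calls. The groupings of embryos described below gave up to 984 genes for that step, so 1 shuffle does not bound the false calls. Shifts of 1 SD in 100 of 200 simulated list scores were recovered in 100% of cases with 4.0% false calls. Camera found 24 of 24 lists shifted by 1 log2 unit, with 0 of 62 false. Both were scored at unadjusted p under 0.05. The largest list differences reported below, -0.36 log2 units, are smaller than the shift given to camera, so its recovery at that size was not tested. For nucleolar genes at the 2-cell stage that difference is also smaller than 1 SD of the list score (0.83 in control and 0.79 in low protein embryos). Recovery by the permutation test at that size was not tested either. Effects of the oocyte donor were recovered in 80.5%, 88.5% and 82% of cases with 51, 39 and 207 false calls at the 2-cell (10282 genes), 4-cell (9805 genes) and morula (9525 genes) stages, so those counts are read only against reassigned donors.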

Results

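Single embryos were profiled by RNA sequencing after in vitro fertilization, in which oocytes from FVB females kept on control diet met sperm of FVB males fed a control or a low protein diet. FVB is an inbred mouse strain, and the embryos grew in KSOM, a culture medium for preimplantation development. The oocyte donors and the culture were shared between diets, so the father's diet was the planned difference. Of 280 embryos, 139 had control and 141 had low protein sires. Control and low protein embryos numbered 41 and 39 at the 2-cell stage, 42 and 40 at the 4-cell stage, 2 and 2 at the 8-cell stage, 38 and 35 at the morula stage, 14 and 22 at the blastocyst stage, and 2 and 3 among late blastocysts. They came from 20 sires, 10 per diet, joined here into 10 pairs by the stem of their identifiers. That these are matched pairs is an assumption that no source states, and every count or exact test by sire pair rests on it. By that pairing the pair used most gave 38.6% of all embryos. Most oocyte donors gave embryos of both diets, 16 of 17 at the 2-cell stage, 16 of 17 at the 4-cell stage, 15 of 15 at the morula stage and 4 of 6 at the blastocyst stage. The sire is the unit that received the diet, whereas the tests on embryos below treat embryos of 1 sire as independent.

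Each embryo carried values for 11076 genes in TPM, a unit scaled to a fixed total per embryo that keeps no record of sequencing depth, so depth is unknown. Genes detected at a TPM of 1 or more per embryo averaged 9134 ± 742 (SD, n = 41) in control and 9254 ± 562 (n = 39) in low protein 2-cell embryos, and 8354 ± 1036 (n = 38) and 8598 ± 539 (n = 35) in morulae, with extremes of 3626 and 10204. The ribosomal RNA precursor Rn45s took between 0.04% and 34.5% of an embryo's total and averaged 8.87 ± 10.6% (SD, n = 42) in control and 7.18 ± 9.43% (n = 40) in low protein 4-cell embryos. The highest shares came from 1 plate, and the median over 4-cell embryos was 2.13%, against 3.64% in late blastocysts. The median Pearson correlation of log2 values between embryos of 1 group lay between 0.828 in control 2-cell embryos (n = 41) and 0.946 in the low protein 8-cell pair (n = 2).

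Low protein sires differed from their control partners by -5.3% in body weight (geometric mean of 10 pairs, range -15.0% to 6.3%) and were lighter in 8 of 10 pairs (two-sided exact sign flip test, p = 0.043, adjusted over the 3 measures p = 0.129). Testis weight differed by -4.0% and fat pad weight by -15.0%, with 6 and 7 of 9 pairs lower (same exact test, p = 0.203 for each), so none of the measures passed after adjustment.

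Between the 2-cell and 4-cell stages, control embryos lost most oocyte transcripts and most transcripts of the 2-cell stage, and gained those of ribosomes and mitochondria. Of 22 maternal transcripts 19 fell and 1 rose. Obox5, an oocyte homeobox gene, fell from 7383 ± 2727 TPM (SD, n = 41) to 28.9 ± 23.1 TPM (n = 42), with a log2 fold change of -8.20 ± 0.26 (SE, limma adjusted p = 3.97e-63). Bmp15, a growth factor secreted by oocytes, fell from 2238 ± 1275 to 16.7 ± 13.6 TPM (adjusted p = 2.28e-60). Of 33 genes linked to MERVL, an endogenous retrovirus active at the 2-cell stage, 30 fell and 1 rose. Zscan4d (chromosome 7, 11161374 to 11166159 in mm10), which acts at telomeres, fell from 732 ± 351 to 8.00 ± 6.92 TPM. Zscan4c went from 588 ± 418 to 2.18 ± 3.33 TPM, Zfp352 from 492 ± 204 to 10.2 ± 40.8 TPM and Tdpoz4 (chromosome 3, 93796398 to 93797510) from 273 ± 166 to 116 ± 173 TPM. All 79 cytosolic ribosomal protein genes rose, with a median log2 fold change of 3.90. Rpl5 went from 38.4 ± 22.3 to 1000 ± 265 TPM (5.02 ± 0.13 SE, adjusted p = 5.78e-72) and Rps3 from 43.2 ± 34.7 to 941 ± 285 TPM. All 20 nucleolar genes rose too, among them Nolc1 from 65.3 ± 46.8 to 514 ± 97.0 TPM.

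Genes of oxidative phosphorylation rose in 52 of 68 cases and fell in 1, with Uqcrc1, a subunit of respiratory complex III, going from 7.01 ± 12.2 (SD, n = 41) to 258 ± 97.1 TPM (n = 42). Glycolysis genes fell in 8 of 17 cases and rose in 2. Ldhb, a lactate dehydrogenase subunit, fell from 3026 ± 1785 to 86.2 ± 37.6 TPM and the glucose transporter Slc2a1 from 67.4 ± 34.1 to 2.15 ± 3.47 TPM. Heat shock proteins split into 3 that rose and 3 that fell of 12, with Hspa8 going from 466 ± 310 to 7885 ± 3177 TPM. Of 14 inner cell mass genes 11 rose and 1 fell, led by the pluripotency gene Dppa5a, which went from 246 ± 236 to 5304 ± 1450 TPM. Of 17 trophectoderm genes 3 rose and 5 fell (4 and 4 after quantile normalization), while Tead4 rose from 1.53 ± 3.13 to 261 ± 101 TPM. Tead4 (chromosome 6, 128224288 to 128300823) is the factor that opens the trophectoderm program. Other fates of the list members were, as rose and fell, 3 and 3 of 12 for primitive endoderm, 4 and 5 of 13 for polarity, 9 and 7 of 22 for cholesterol, 8 and 16 of 41 for replication-dependent histones, 9 and 3 of 17 for S phase, and 8 and 5 of 20 for G2 and M phase. The same counts were 6 and 4 of 16 for p53 targets, 6 and 5 of 14 for the integrated stress response, 3 and 5 of 14 for DNA methylation, 6 and 4 of 12 for small RNA processing, 5 and 4 of 11 for paternally and 2 and 4 of 9 for maternally expressed imprinted genes, and 0 and 1 of 3 for sperm transcripts. Cldn7 of the tight junctions rose from 5.28 ± 6.34 to 181 ± 105 TPM, while the polarity kinase Prkci fell from 43.5 ± 16.7 to 3.79 ± 3.14 TPM. Among imprinted genes Mest fell from 156 ± 53.5 to 3.88 ± 4.28 TPM and Igf2r rose from 1.32 ± 1.52 to 62.6 ± 43.7 TPM. Tet3, which oxidizes methylated cytosine, fell from 91.01 ± 32.1 to 4.70 ± 3.11 TPM.

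In all, the stage change from 2-cell to 4-cell comprised 3803 genes that rose and 4079 that fell of 11054 tested in control embryos (adjusted p under 0.05 and an absolute log2 fold change of 1 or more). The largest rise was that of Bhmt, a homocysteine methyltransferase (chromosome 13, 93616675 to 93637961), from 6.22 ± 15.6 (SD, n = 41) to 1421 ± 556 TPM (n = 42), with a log2 fold change of 8.80 ± 0.25 (SE, limma adjusted p = 4.53e-67). Next came Nt5c3b, from 1.97 ± 4.14 to 362 ± 119 TPM, and Hand1, a helix-loop-helix factor, from 1.34 ± 2.68 to 377 ± 171 TPM. Vnn1, Syngr1, Isyna1, Tsr2, Nt5c and Slc39a4 followed, with log2 fold changes of 7.44, 7.13, 7.05, 7.01, 6.93 and 6.65. The largest falls belonged to Gm21312, from 4497 ± 2281 to 12.3 ± 34.1 TPM (adjusted p = 9.98e-62), and Gm4340, from 1073 ± 576.8 to 1.60 ± 8.51 TPM. They were followed by Tcl1b2, from 3619 ± 1277 to 9.93 ± 9.25 TPM, and Tcstv1, from 749 ± 296 to 4.56 ± 13.8 TPM. Gm428, AA545190, BB287469, Gm11758, Gm1965 and E330034G19Rik fell too, with log2 fold changes of -9.24, -8.95, -8.92, -8.81, -8.76 and -8.39. Values of single copies in the Zscan4, Tdpoz, Tcl1b, Tcstv, Obox, Usp17l and Gm21312 families are uncertain, because reads from near-identical copies cannot be told apart. TPM values share a fixed total, so a rise of abundant ribosomal transcripts lowers the share of all others, and fold changes on the scale of log2 of TPM plus 1 understate genes of low level.

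From the 4-cell to the morula stage, most markers of the first epithelium rose in control embryos while most maternal transcripts fell. Of 17 trophectoderm genes 12 rose and 1 fell. Cdx2, the homeobox regulator of trophectoderm, rose from 3.31 ± 5.94 (SD, n = 42) to 85.1 ± 59.03 TPM (n = 38, log2 fold change 4.75 ± 0.32 SE, limma adjusted p = 7.82e-29). The keratin gene Krt8 (chromosome 15, 101996698 to 102004482) rose from 9.11 ± 12.9 to 362 ± 284 TPM (5.58 ± 0.37 SE, adjusted p = 7.40e-29). Of the maternal transcripts 18 of 22 fell and 1 rose, with Npm2 dropping from 55.1 ± 27.8 to 3.80 ± 2.73 TPM, whereas Khdc3 of the subcortical maternal complex rose from 132 ± 71.2 to 1525 ± 969 TPM. MERVL-linked genes fell in 15 of 33 cases and rose in 0 (14 and 1 after quantile normalization), Tdpoz4 reaching 4.82 ± 11.3 TPM. Among inner cell mass genes 6 of 14 rose and 5 fell. Tfcp2l1 rose from 4.16 ± 6.35 to 82.1 ± 32.2 TPM and Pou5f1 from 273 ± 144 to 1030 ± 463 TPM, while Prdm14 fell from 15.3 ± 11.2 to 1.98 ± 2.77 TPM. Primitive endoderm genes rose in 6 and fell in 2 of 12 cases, with Gata4 falling from 141 ± 65.9 to 1.59 ± 2.06 TPM and Lrp2 rising from 0.339 ± 0.702 to 12.6 ± 10.4 TPM. Xist, the RNA that silences 1 X chromosome, rose from 8.63 ± 19.7 to 47.04 ± 89.9 TPM (adjusted p = 0.00224).

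Polarity genes rose in 6 and fell in 1 of 13 cases (9 and 1 after quantile normalization), among them Ezr from 0.905 ± 1.56 (SD, n = 42) to 27.1 ± 23.8 TPM (n = 38). Glycolysis genes rose in 6 and fell in 3 of 17 cases, with Gapdh going from 53.9 ± 107 to 346 ± 281 TPM. Oxidative phosphorylation genes rose in 13 and fell in 0 of 68 cases (24 and 0 after quantile normalization). No ribosomal protein gene passed the threshold, at 0 and 0 of 79. The other lists are given as rose and fell, with counts after quantile normalization in brackets. They read 3 and 0 of 12 for heat shock proteins, 0 and 6 of 20 for nucleolar genes (0 and 3) and 4 and 0 of 22 for cholesterol (10 and 0). They read 5 and 2 of 41 for histones, 1 and 3 of 17 for S phase (2 and 0) and 0 and 9 of 20 for G2 and M phase (1 and 5). They read 6 and 3 of 16 for p53 targets, 1 and 5 of 14 for the integrated stress response, 2 and 7 of 14 for DNA methylation (4 and 3), 1 and 3 of 12 for small RNA processing, 1 and 1 of 11 for paternally (3 and 1) and 0 and 4 of 9 for maternally expressed imprinted genes, and 0 and 1 of 3 for sperm transcripts. Hsp90aa1 rose from 895 ± 451 to 6468 ± 2407 TPM, and the mitotic activator Cdc20 fell from 1638 ± 661 to 501 ± 220 TPM.

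The stage change from 4-cell to morula comprised 1098 genes that rose and 2923 that fell, with a median over all genes of -0.33 log2 units, so falls of that size are shared by the typical gene. Only 27.3% of the changes were rises, against 50.2% after quantile normalization. The largest rises were those of the proteoglycan gene Sdc4, from 2.00 ± 2.96 (SD, n = 42) to 310 ± 217 TPM (n = 38, limma adjusted p = 1.07e-45), and Ass1 of arginine synthesis, from 1.63 ± 2.95 to 201.0 ± 118 TPM. S100a11, Perp, Elf3, Gsto1, Ly6a and Bmyc rose with log2 fold changes of 5.49, 5.45, 5.44, 4.89, 4.80 and 4.78. The largest falls were those of Omt2a, from 355.0 ± 250.0 to 4.28 ± 5.23 TPM, Omt2b, from 2031 ± 1262 to 45.6 ± 61.96 TPM, and the zinc finger gene Klf17, from 530.4 ± 152 to 10.5 ± 19.5 TPM (adjusted p = 3.43e-57). B020004C17Rik, Gcm1, Slc19a3, Lbhd1, Gm10697 and Fam212a followed at -6.32, -5.52, -5.47, -5.38, -5.29 and -5.24. Omt2a and Omt2b are close copies of each other, so their separate values are uncertain.

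From morula to blastocyst, trophectoderm genes of control embryos rose in 11 of 17 cases and fell in 0. Gata3 (chromosome 2, 9857078 to 9890034) rose from 89.9 ± 73.6 (SD, n = 38) to 864 ± 254 TPM (n = 14, log2 fold change 4.85 ± 0.44 SE, limma adjusted p = 2.37e-18). Krt8 went from 362 ± 284 to 6159 ± 2495 TPM. Glycolysis genes rose in 10 of 17 cases and fell in 2, with Gapdh going from 346 ± 281 to 2779 ± 623 TPM and Aldoa from 655 ± 321 to 2336 ± 481 TPM. Oxidative phosphorylation genes rose in 22 and fell in 0 of 68 cases, such as Cox5a from 1348 ± 478 to 2520 ± 417 TPM. Inner cell mass genes rose in 1 and fell in 4 of 14 cases (2 and 2 after quantile normalization), with Klf2 falling from 19.2 ± 21.7 to 1.35 ± 1.01 TPM. Primitive endoderm genes rose in 4 and fell in 1 of 12 cases, among them Sox17 from 0.0453 ± 0.279 to 11.6 ± 9.71 TPM. Polarity genes rose in 6 and fell in 0 of 13 cases, with Ezr going from 27.1 ± 23.8 to 113 ± 37.6 TPM.

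Nucleolar genes fell in 10 of 20 cases (6 after quantile normalization), and Nolc1 dropped from 179 ± 91.6 (SD, n = 38) to 62.7 ± 11.9 TPM (n = 14). Ribosomal protein genes fell in 6 of 79 cases (1 after quantile normalization), among them Rps24 from 1643 ± 395 to 889 ± 248 TPM. MERVL-linked genes fell in 11 and rose in 0 of 33 cases, with Sp110 going from 370 ± 279 to 35.7 ± 29.3 TPM. The other lists, as rose and fell, read 1 and 4 of 22 for maternal transcripts, 1 and 2 of 12 for heat shock proteins, 0 and 5 of 22 for cholesterol (2 and 2 after quantile normalization), 5 and 1 of 41 for histones, 0 and 3 of 17 for S phase and 1 and 2 of 20 for G2 and M phase. They read 0 and 6 of 16 for p53 targets, 0 and 4 of 14 for the integrated stress response, 3 and 0 of 14 for DNA methylation, 0 and 1 of 12 for small RNA processing (0 and 0), 3 and 2 of 11 for paternally and 1 and 1 of 9 for maternally expressed imprinted genes, and 0 and 0 of 3 for sperm transcripts. Tdg, a DNA glycosylase of active demethylation, rose from 2.66 ± 3.07 to 58.3 ± 17.9 TPM, and Cdkn1a, a p53 target that halts the cell cycle, fell from 145 ± 129 to 46.6 ± 44.7 TPM.

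The stage change from morula to blastocyst comprised 820 genes that rose and 1873 that fell, with a median of -0.24 log2 units over all genes. Rises made up 30.4% of the changes, against 49.7% after quantile normalization and 47% without the plate covariate, so the balance of directions depends on these settings. Quantile normalization by its design moves the median toward 0, here to -0.03, so it cannot tell a scaling effect from a real shift. The largest rises were those of the alcohol dehydrogenase gene Adh1, from 0.634 ± 1.53 (SD, n = 38) to 1193 ± 846 TPM (n = 14, limma adjusted p = 2.82e-38), and Krt18, the partner of Krt8, from 173 ± 140 to 5465 ± 2480 TPM. BC053393, Lgals1, Dppa1, Tspan8, Slc15a2, Anxa6 and Id2 rose with log2 fold changes of 7.17, 6.19, 5.98, 5.52, 5.48, 5.06 and 4.95. The largest falls were those of Obox6, from 546 ± 565 to 8.73 ± 12.9 TPM, Cdk2ap1, from 937 ± 448 to 31.1 ± 39.5 TPM, and Cited1, from 420.4 ± 251 to 18.6 ± 15.6 TPM (adjusted p = 2.53e-12). Stmn3, Bex6, Abhd6, 2610318N02Rik, Gm11517, Trim43c and Hand1 followed at -5.78, -4.86, -4.50, -4.47, -4.42, -4.37 and -4.25. The control blastocysts came from 2 sires only.

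**Figure D1:**
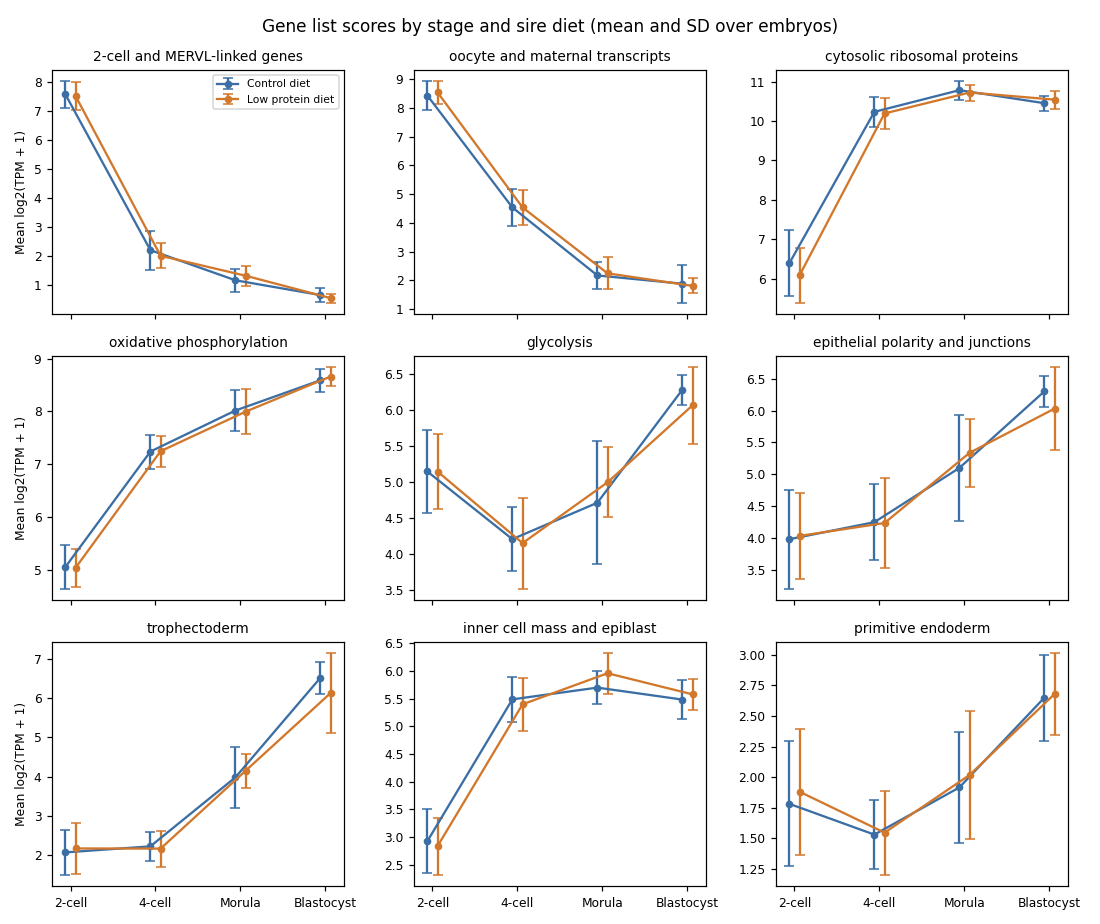
Mean list score in log2(TPM + 1) per stage for 9 gene lists, control embryos in blue and low protein embryos in orange, with SD over embryos. The ribosomal protein genes rose in 79 of 79 cases between the 2-cell and 4-cell stages.

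At the 2-cell stage no gene separated embryos by the father's diet after adjustment in the reported fit. Il6ra, the interleukin 6 receptor (chromosome 3, 89864059 to 89913196), stood at 14.6 ± 15.3 TPM (SD, n = 41) in control and 8.06 ± 7.54 TPM (n = 39) in low protein embryos (log2 fold change -0.97 ± 0.22 SE, limma adjusted p = 0.228). Msx1, a homeobox gene (chromosome 5, 37820485 to 37824583), stood at 24.5 ± 44.9 and 43.7 ± 61.6 TPM (1.35 ± 0.34, adjusted p = 0.432). Msx1 was higher with low protein sires in 8 of 8 sire pairs and Il6ra lower in 7 of 8. Named genes were picked by p from the same embryos, so such pair counts, here and at later stages, are not independent support. Some pairs also hold 1 embryo of a diet. Cisd2, an iron-sulfur protein of the mitochondrial outer membrane, stood at 43.3 ± 16.5 and 56.1 ± 19.1 TPM (adjusted p = 0.432). The translation factor gene Eif3h stood at 156 ± 104 and 121 ± 61.1 TPM (adjusted p = 0.599). Nme3, Zbtb8a, Ccdc73, 4933434E20Rik, D1Pas1 and Pitpnb had log2 fold changes of 1.03, -0.99, 0.65, -0.40, -0.99 and -1.32, each at an adjusted p of 0.599. The MERVL-linked genes named beforehand did not pass either. Zscan4d stood at 732 ± 351 and 746 ± 372 TPM (0.07 ± 0.16, adjusted p = 0.939), Zscan4c at 588 ± 418 and 601 ± 404 TPM (adjusted p = 0.954). Tdpoz4 stood at 273 ± 166 and 205.5 ± 141 TPM (-0.46 ± 0.22, p = 0.0388, adjusted p = 0.706) and Zfp352 at 492 ± 204 and 411.5 ± 208 TPM (-0.32 ± 0.16, p = 0.0498, adjusted p = 0.706). Limma called 0 of 10314 genes, with 717 at unadjusted p under 0.05, 286 higher and 431 lower. The smallest adjusted p, 0.0739, was that of Enpp1 (chromosome 10, 24637914 to 24712159), a gene chosen after its values were seen because its means of 0.621 ± 1.31 and 2.37 ± 2.41 TPM are too low for the naming rule. Enpp1 passed in some alternatives, at limma adjusted p of 0.0121 with a pseudocount of 0.1, 0.0234 without plate 3 and 0.0308 without sire pair FVB9-9. For 91.4% of genes the 95% interval excluded more than a 2-fold difference in TPM plus 1, a looser bound on TPM itself for genes of low level. Among 7143 genes with a mean of at least 10 TPM in 1 group the share was 91.6%. These intervals treat embryos of 1 sire as independent.

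Ribosome-related lists leaned lower in low protein 2-cell embryos without passing. Of 79 ribosomal protein genes 76 were lower and 3 higher, with a list difference of -0.34 ± 0.15 (SE, two-sided permutation p = 0.0249, adjusted p = 0.369), and none passed over all genes or adjusted over the list alone (0 and 0), although 28 reached an unadjusted p under 0.05. Rps16 (chromosome 7, 28350652 to 28353155) stood at 315 ± 156 (SD, n = 41) and 237 ± 88 TPM (n = 39) and Rpl24 at 145 ± 151 and 90.1 ± 65.5 TPM. All 20 nucleolar genes were lower, at -0.36 ± 0.15 (permutation p = 0.0170, adjusted p = 0.369), with 0 members passing over all genes and 0 adjusted over the list alone. Nhp2 stood at 258 ± 373 and 139 ± 134 TPM and Rrp9 at 112 ± 110 and 80 ± 94.2 TPM. By sire, both lists were lower in 7 of 8 pairs (two-sided exact sign flips over 8 pairs, p = 0.0469 for ribosomal proteins and 0.0313 for nucleolar genes, adjusted p = 0.672 for each). Camera, a test that allows for correlation within a list, gave an adjusted p of 0.682 for both. MERVL-linked genes differed by -0.08 (permutation p = 0.441, adjusted p = 0.817), 12 higher and 21 lower, with AF067063, Usp17lc and Tdpoz2 at -0.38, -0.32 and -0.66.

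No gene separated 4-cell embryos by the father's diet after adjustment. Taco1, which activates translation of mitochondrial COX1 (chromosome 11, 106066061 to 106073612), stood at 15.6 ± 12.6 TPM (SD, n = 42) in control and 9.31 ± 10.3 TPM (n = 40) in low protein embryos (log2 fold change -1.02 ± 0.24 SE, limma adjusted p = 0.317), lower in 8 of 8 sire pairs. Apopt1, also mitochondrial, stood at 21.3 ± 29.1 and 32.6 ± 41.1 TPM (0.86 ± 0.20, adjusted p = 0.317), and Sc5d of sterol synthesis at 5.59 ± 4.21 and 2.96 ± 3.46 TPM (-0.92 ± 0.23, adjusted p = 0.317). Slirp, which stabilizes mitochondrial mRNA, stood at 135 ± 54.01 and 190.1 ± 94.3 TPM (adjusted p = 0.842). Rpp25, a subunit of RNase MRP and of the tRNA-processing RNase P, stood at 34.9 ± 42.1 and 19.3 ± 21.4 TPM (adjusted p = 0.842) and was lower in 8 of 8 pairs. Snhg12, Defb25, Tmem92, 3110009E18Rik and Sdccag3 had log2 fold changes of -1.01, -1.49, -0.77, -1.18 and -0.67. Xist stood at 8.63 ± 19.7 and 20.9 ± 38.2 TPM (0.93 ± 0.43, p = 0.0342, adjusted p = 0.939). Tdpoz4 stood at 116 ± 173 and 77.9 ± 125 TPM (-0.56 ± 0.30, adjusted p = 0.987). Zscan4d stood at 8.00 ± 6.92 and 7.13 ± 6.68 TPM (adjusted p = 0.987), and Zscan4c and Zfp352 differed by -0.07 and -0.24. Limma called 0 of 9820 genes, with 511 at unadjusted p under 0.05, 192 higher and 319 lower. For 96.3% of genes the 95% interval over embryos excluded more than a 2-fold difference in TPM plus 1. The share was 97.1% among 6533 genes with a mean of at least 10 TPM in 1 group. MERVL-linked genes differed by -0.24 (two-sided permutation p = 0.0992, adjusted p = 0.449), with 6 higher and 19 lower, 0 passing over all genes and 2 adjusted over the list alone, Tmem92 and Tcstv3. The integrated stress response differed by -0.17 (permutation p = 0.0498, adjusted p = 0.389), 3 higher and 10 lower, and 0 members passed over all genes or adjusted over the list alone.

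The 8-cell stage had 2 embryos of 1 sire per diet, so its values describe those embryos rather than a diet. Mat2a, which makes the methyl donor S-adenosylmethionine (chromosome 6, 72432799 to 72439558), stood at 1757 ± 272 TPM (SD, n = 2) in control and 751 ± 43.8 TPM (n = 2) in low protein embryos (log2 fold change -1.22 ± 0.17 SE, limma adjusted p = 0.241). Cphx2, a homeobox gene, stood at 127 ± 47.5 and 22.1 ± 2.09 TPM (limma adjusted p = 0.241). Tex101, Rbsn and Slc25a5 differed by -2.63, -1.80 and 1.01 log2 units, and Snhg6, Rab26os and Hesx1 were listed at 0 in both low protein embryos and Gm7367 at 0 in both control embryos. Limma called 0 of 9768 genes, with 747 at unadjusted p under 0.05, of which 227 were higher, and the median difference of all genes was -0.12. Only 3.3% of genes had a 95% interval within a 2-fold difference in TPM plus 1.

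In morulae too no gene passed in the reported fit, and 9 of the 10 genes with the lowest p were higher in low protein embryos. Some alternatives change this call, as Spic and Pmm1 passed with oocyte donor in place of plate (limma adjusted p = 0.0335 for both) and H2-D1 with runs of embryos as replicates (limma adjusted p = 0.0252). With sire means as replicates none passed, at limma adjusted p of 0.331 for H2-D1 and 0.419 for Spic, Pmm1 and Id3. Id3, an inhibitor of helix-loop-helix factors (chromosome 4, 136143497 to 136145755), stood at 103 ± 51.6 TPM (SD, n = 38) in control and 189.9 ± 122 TPM (n = 35) in low protein embryos (log2 fold change 0.82 ± 0.18 SE, limma adjusted p = 0.0619), higher in 8 of 8 sire pairs. H2-D1, a class I histocompatibility gene (chromosome 17, 35262730 to 35267499) whose value is uncertain because of its paralogs, stood at 156 ± 98.1 and 250.5 ± 137 TPM (0.85 ± 0.19, adjusted p = 0.0619). Pmm1, a phosphomannomutase gene (chromosome 15, 81951108 to 81960930), stood at 1240 ± 491 and 1564 ± 479 TPM (0.38 ± 0.08, adjusted p = 0.0619). Fgf3, a fibroblast growth factor, stood at 10.7 ± 8.77 and 20.9 ± 12.1 TPM, Etv5, a transcriptional target of that pathway, at 11.2 ± 9.62 and 20.9 ± 14.6 TPM, and the phosphatase gene Ptpn6 at 24.5 ± 14.7 and 40.2 ± 17.4 TPM (adjusted p = 0.126 for each). Spic, Pnp and Pex16 had log2 fold changes of 1.25, 0.79 and 0.46. Tpt1, which encodes the translationally controlled tumor protein, was the exception at 1741 ± 485 and 1427 ± 267 TPM (-0.27 ± 0.07, adjusted p = 0.184), lower in 8 of 8 pairs. Xist and Tdpoz4 differed by -0.19 and 0.25 (adjusted p = 0.930 and 0.820). Limma called 0 of 9552 genes, with 996 at unadjusted p under 0.05, 904 higher and 92 lower, against a median difference over all genes of 0.12 log2 units. For 93.3% of genes the 95% interval over embryos excluded more than a 2-fold difference in TPM plus 1. The share was 92.1% among 5826 genes with a mean of at least 10 TPM in 1 group.

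By permutation over embryos, inner cell mass genes had the smallest p of all lists, with 12 of 14 higher in low protein morulae and a list difference of 0.26 ± 0.08 (SE, two-sided permutation p = 0.00083, adjusted p = 0.0714). Of its members 0 passed over all genes and 3 passed adjusted over the list alone. These were the Nodal coreceptor Tdgf1 (chromosome 9, 110939603 to 110946158) at 43.4 ± 34.2 (SD, n = 38) and 76.3 ± 59.1 TPM (n = 35), Dppa4 at 388 ± 101 and 460.5 ± 119 TPM, and Utf1 at 60.8 ± 29.8 and 81.8 ± 31 TPM. By sire the list was higher in 6 of 8 pairs (two-sided exact sign flips over 8 pairs, p = 0.0469, adjusted p = 0.672), while the integrated stress response, heat shock and nucleolar lists had smaller p, at 0.0234, 0.0312 and 0.0312, each higher in 7 of 8 pairs at the same adjusted p. For inner cell mass genes the difference was 0.17 after quantile normalization, and camera gave an adjusted p of 0.908, so the adjusted p ranged from 0.0645 to 0.908 over the alternatives. Heat shock proteins differed by 0.24 ± 0.08 (permutation p = 0.00296, adjusted p = 0.127), 11 of 12 higher, with 0 passing over all genes and 1, Dnajb1 at 72.8 ± 32.8 and 97.4 ± 39.5 TPM, adjusted over the list alone. Nucleolar genes differed by 0.18 (permutation p = 0.0237, adjusted p = 0.369), 19 of 20 higher. MERVL-linked genes differed by 0.28 (p = 0.0378, adjusted p = 0.389), 14 of 16 higher, where Tdpoz3 was the 1 member passing adjusted over the list alone. G2 and M phase genes differed by 0.22 (p = 0.0451, adjusted p = 0.389), 18 of 20 higher, with Ube2c at 976 ± 361 and 1220 ± 251 TPM the 1 member passing adjusted over the list alone. The integrated stress response differed by 0.27 (p = 0.0479, adjusted p = 0.389), 12 of 13 higher, with 0 passing either way. These differences are to be read against the median of 0.12 over all genes.

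At the blastocyst stage, with 2 complete sire pairs, Mettl7a3, a putative methyltransferase gene (chromosome 15, 100334929 to 100340375), stood at 9.92 ± 4.80 TPM (SD, n = 14) in control and 3.03 ± 4.25 TPM (n = 22) in low protein embryos (log2 fold change -1.60 ± 0.36 SE, limma adjusted p = 0.663). The chemokine gene Cxcl16 stood at 11.2 ± 7.53 and 5.95 ± 4.60 TPM (adjusted p = 0.720). The chromatin remodeler gene Smarcb1 stood at 108 ± 20.02 and 116 ± 56.9 TPM, and Necap2 of clathrin coats at 44.6 ± 13.9 and 63.1 ± 11.5 TPM (adjusted p = 0.663 for both). Enpp1, Kdelr3 and E330023G01Rik had log2 fold changes of 1.11, -0.88 and -1.07. For Timm17b, at 68.5 ± 14.7 and 88.7 ± 79.7 TPM, and Apoe, at 1094 ± 797 and 1431 ± 1840 TPM, the plate-adjusted changes of -0.52 and -0.80 run against the group means, because the low protein blastocysts of 1 plate have no control on it. Xist also ran against its group means, at 35.2 ± 20.8 and 56.6 ± 112 TPM with -1.92 ± 0.84 (limma p = 0.0286, adjusted p = 0.9998). Xist was present in 12 of 14 control and 12 of 22 low protein blastocysts, and Y-linked transcripts in 3 of 14 and 11 of 22. The Xist change of -1.92 compares embryos within plates, whereas these counts cover all plates. Whether the mix of sexes within plates makes that change was not tested. Limma called 0 of 9378 genes, with 322 at unadjusted p under 0.05, 144 higher and 178 lower. For 90.1% of genes the 95% interval over embryos excluded more than a 2-fold difference in TPM plus 1. The share was 93.4% among 5474 genes with a mean of at least 10 TPM in 1 group. MERVL-linked genes differed by -0.36 (two-sided permutation p = 0.0469, adjusted p = 0.389), 1 higher and 8 lower, and the integrated stress response by -0.21 (p = 0.0257, adjusted p = 0.369), 3 higher and 9 lower, with 0 members of both passing over all genes or adjusted over the list alone.

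Late blastocysts numbered 2 and 3 from 1 sire per diet. Hnrnpul1, an RNA-binding protein gene (chromosome 7, 25721165 to 25754757), stood at 2.24 ± 0.205 TPM (SD, n = 2) in control and 43.8 ± 5.11 TPM (n = 3) in low protein embryos (log2 fold change 3.79 ± 0.50 SE, limma adjusted p = 0.123). Adam15, a membrane protease gene, stood at 13.2 ± 4.49 and 112 ± 26.8 TPM and the nucleolar chaperone gene Npm3 at 228 ± 35.5 and 46.2 ± 18.3 TPM (limma adjusted p = 0.173 for each). Sh3bp1, Gm2027, Slc44a1, Prr5 and Epn1 differed by 2.92, 3.71, 3.22, 2.81 and 3.65 log2 units, and Raet1e was listed at 0 in all 3 low protein embryos. Xist stood at 82.7 ± 65.97 and 276 ± 7.72 TPM (limma adjusted p = 0.191). Limma called 0 of 9452 genes, and 0 to 869 when single embryos were left out, with 1480 at unadjusted p under 0.05, of which 1275 were higher, and the median difference of all genes was 0.38, so most of these differences run the way of a shared shift. Only 0.7% of genes had a 95% interval within a 2-fold difference in TPM plus 1.

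Across 86 list tests 0 passed, and 11 had a two-sided permutation p under 0.05. Maternal transcripts differed by 0.07, -0.04, 0.08 and -0.17 at the 2-cell, 4-cell, morula and blastocyst stages (adjusted p = 0.817, 0.952, 0.817 and 0.777). Oxidative phosphorylation was the steadiest list at -0.01, -0.02, -0.02 and 0.01 (adjusted p from 0.952 to 0.958). Ribosomal proteins differed by -0.08, -0.07 and -0.01 after the 2-cell stage (adjusted p = 0.703, 0.703 and 0.952), nucleolar genes by -0.04 and 0.00 at the 4-cell and blastocyst stages (adjusted p = 0.817 and 0.978), and heat shock proteins by -0.14, 0.00 and -0.05 outside morulae (adjusted p = 0.583, 0.993 and 0.803). Glycolysis differed by -0.06, -0.04, 0.26 and 0.05, cholesterol synthesis by 0.02, -0.14, 0.26 and 0.00, and S phase by -0.11, 0.01, 0.25 and -0.01, with their smallest adjusted p in morulae at 0.419, 0.402 and 0.393. G2 and M phase differed by -0.11, -0.02 and 0.06 outside morulae (adjusted p = 0.449, 0.952 and 0.817). Histones differed by 0.04, -0.03, -0.02 and 0.03 (adjusted p = 0.952 throughout) and p53 targets by -0.05, -0.18, 0.15 and -0.19 (smallest adjusted p = 0.402 at the 4-cell stage). The integrated stress response differed by -0.07 at the 2-cell stage (adjusted p = 0.817), DNA methylation by -0.02, 0.04, 0.19 and 0.07 (smallest adjusted p = 0.402) and small RNA processing by 0.01, -0.03, 0.20 and 0.07 (smallest adjusted p = 0.646). Paternally expressed imprinted genes differed by -0.08, -0.04, 0.05 and 0.09 and maternally expressed ones by 0.07, 0.03, 0.09 and -0.10 (smallest adjusted p = 0.817 and 0.803). Trophectoderm differed by 0.09, -0.13, 0.16 and 0.11, inner cell mass outside morulae by -0.11, -0.09 and 0.11, primitive endoderm by 0.05, 0.06, 0.12 and 0.13, and polarity by 0.00, 0.01, 0.22 and 0.03 (smallest adjusted p = 0.803, 0.803, 0.777 and 0.449). In blastocysts, where low protein embryos of 1 plate have no control, several plate-adjusted differences run against the group means. Among them are trophectoderm (means of 6.52 in control and 6.13 in low protein embryos), glycolysis, G2 and M phase, DNA methylation, polarity and both imprinted lists. Sperm transcripts, of which 3 were in the table, differed by -0.22 and 0.14 at the first pair of stages (adjusted p = 0.676 and 0.817). After quantile normalization the sign turned for heat shock proteins, glycolysis, histones, small RNA processing and paternally expressed imprinted genes at the 4-cell stage. It also turned for maternal transcripts, both imprinted lists and primitive endoderm in morulae and for cholesterol synthesis in blastocysts, so these lists have no settled direction. No list member passed over all genes. Adjusted over the list alone, Cdc6 of S phase passed at the 2-cell stage (34.5 ± 17.98 TPM, SD, n = 41, against 27.04 ± 20.8 TPM, n = 39). At the 4-cell stage Sc5d of cholesterol synthesis, Cdkn1a of the p53 targets (107 ± 66.6 against 84.8 ± 77.5 TPM) and Id2 of trophectoderm passed in the same way.

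**Figure D2:**
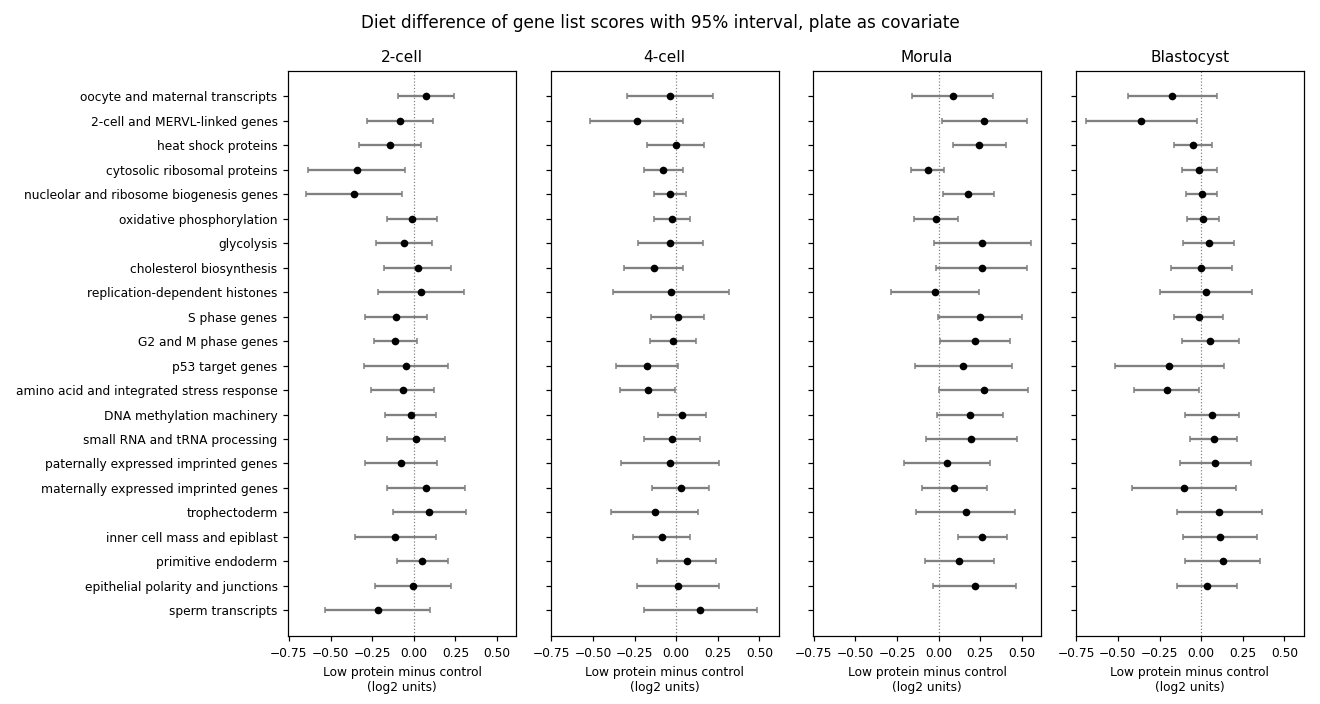
Low protein minus control difference in list score, in log2 units with 95% intervals, for 22 lists at 4 stages with plate as covariate. The inner cell mass list in morulae lies at 0.26, and 0 of 86 tests passed after adjustment.

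**Figure D3:**
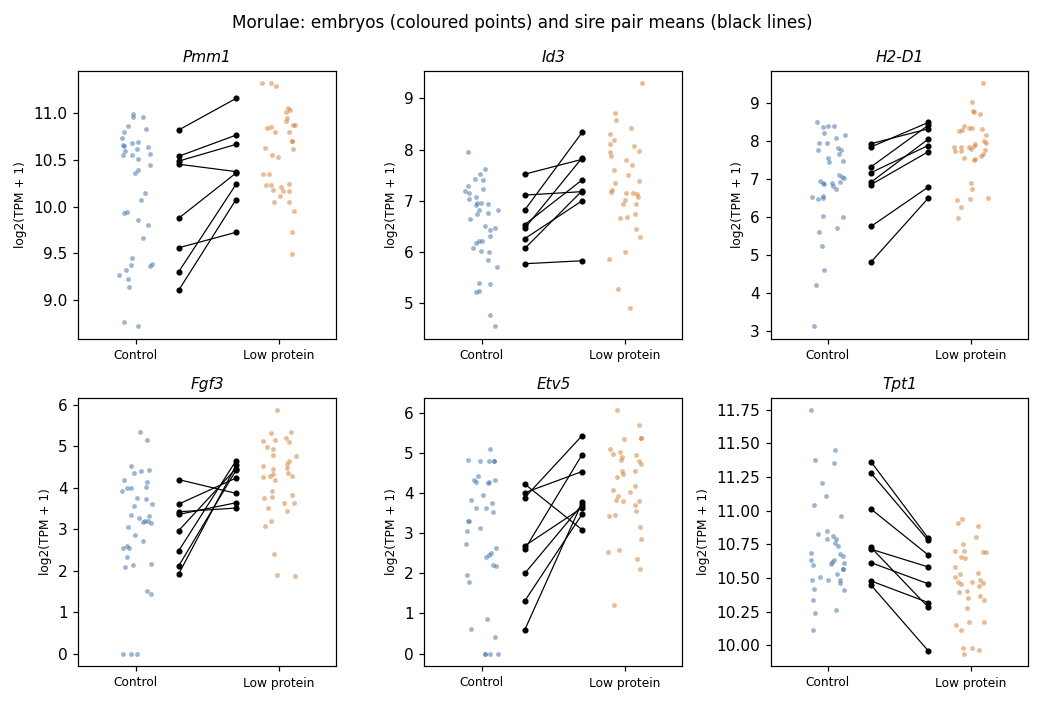
Values in log2(TPM + 1) of Pmm1, Id3, H2-D1, Fgf3, Etv5 and Tpt1 in control and low protein morulae, with points for embryos and black lines for sire pair means. Id3 and H2-D1 were higher in 8 of 8 pairs and Tpt1 lower in 8 of 8. The genes were picked by p from the same embryos, so the pair counts are not independent support.

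For 14 genes the diet difference in log2 of TPM plus 1 differed between stages (limma F test of the diet by stage interaction, adjusted p under 0.05). Msx1 differed by 1.35 at the 2-cell stage, at 24.5 TPM in control (n = 41) and 43.7 TPM in low protein embryos (n = 39), and its means stayed below 1 TPM afterwards (limma adjusted p = 0.0386). Zbtb8a, a zinc finger gene, differed by -0.99, -0.03, 0.67 and -0.29 at the 2-cell, 4-cell, morula and blastocyst stages, and Ccdc86, a nucleolar protein gene, by -0.80, -0.13, 0.57 and -0.08. Atg10 of autophagy differed by 0.44, -0.92 and 0.76 at the 2-cell, 4-cell and blastocyst stages, Rfxank by -0.72 at the 2-cell and 0.41 at the morula stage, and Enpp1 by 0.98 and 1.11 at the 2-cell and blastocyst stages, each at a limma adjusted p of 0.0386. Enpp1 means in control and low protein embryos were only 0.13 and 0.34 TPM at the 4-cell and 0.26 and 0.47 TPM at the morula stage. For Enpp1 and Msx1 the test therefore cannot separate a changing diet effect from levels near 0 at some stages. The translation factor gene Eif3b differed by -0.91 at the 2-cell and 0.52 at the blastocyst stage (limma adjusted p = 0.0478). Embryos of 1 sire are not independent, and with sire means as replicates 1 of the 14, Mir692-3, passed.

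Position along the developmental course was scored from the genes that change between stages. Low protein 2-cell embryos scored -2.77 ± 0.57 (SD, n = 39) and control embryos -2.56 ± 0.71 (n = 41) on the course to the 4-cell stage, a difference of -0.23 or -3.36% of the full step (two-sided permutation p = 0.0540, adjusted p = 0.162). Low protein morulae scored -2.72 ± 0.73 (n = 35) and control morulae -2.48 ± 0.73 (n = 38) on the course to the blastocyst, a difference of -0.28 or -5.10% of the step (permutation p = 0.0434, adjusted p = 0.162). Both were lower in 6 of 8 sire pairs (two-sided exact sign flips over 8 pairs, p = 0.0703 and 0.109), so neither passed. The other 4 scores had adjusted p between 0.881 and 0.903, with differences of -0.01 on both courses at the 4-cell stage, 0.04 in morulae on the course from the 4-cell stage and 0.22 in blastocysts. The blastocyst means ran the other way, at 3.12 ± 0.91 (SD, n = 14) in control and 2.65 ± 1.42 (n = 22) in low protein embryos. Low protein blastocysts of 1 plate have no control on it and scored from 0.0 to 0.46. The other low protein blastocysts scored 2.12 or more, and the lowest control blastocyst 0.41. By sire the blastocyst difference was 0.02, with 1 of 2 pairs higher. Spread among embryos differed by -0.03, 0.07, -0.10 and -0.03 at the 2-cell, 4-cell, morula and blastocyst stages (two-sided permutation, adjusted p = 0.377, 0.126, 0.126 and 0.126). These calls depend on the settings. With a pseudocount of 0.1 the embryo to embryo variability at the 4-cell stage differed by 0.121 and the embryo to embryo variability at the morula stage by -0.188 (permutation adjusted p = 0.0309 for each). Around the mean of stage and diet the embryo to embryo variability at the blastocyst stage reversed to 0.0522 (adjusted p = 0.0158). The number of genes detected differed by 79.5, -145, 228 and -12.8 (adjusted p = 0.648, 0.440, 0.440 and 0.883).

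**Figure D4:**
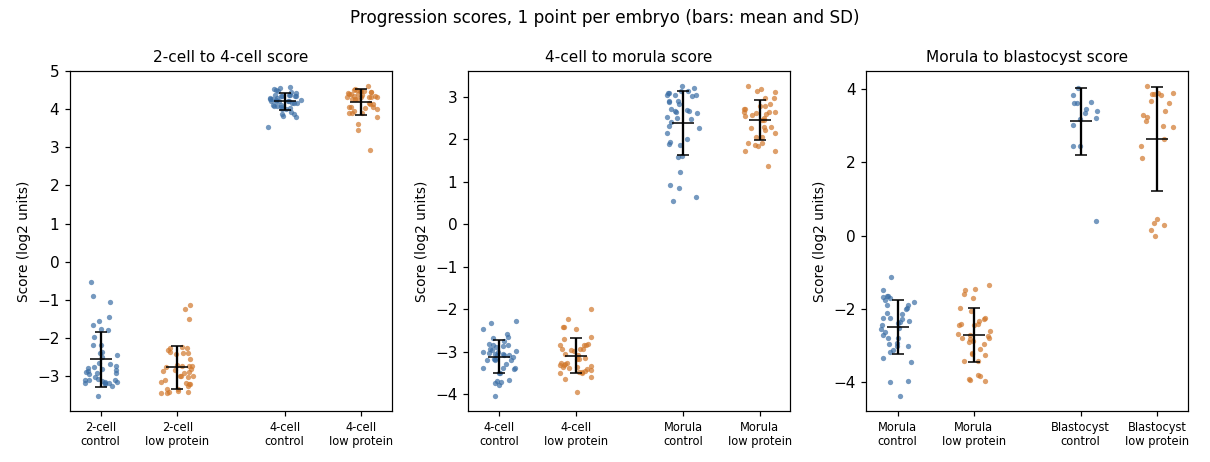
Course scores for embryos of control and low protein sires, with 1 point per embryo and bars for mean and SD. At the morula stage the low protein embryos averaged -2.72 and the control embryos -2.48 on the course to the blastocyst.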

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

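The splits of the embryos and the quantile comparisons below were chosen after the results were seen, while the tests with covariates, left-out sire pairs and oocyte donors were written down before they were run, though with the patterns already known. In each set of 100 groupings the real one is included.

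The diet difference of 14 genes in log2 of TPM plus 1 differed between stages by the limma F test. An adjusted p of 0.0386 was reached by Msx1, Enpp1, Zbtb8a, Ccdc86, Atg10 and Rfxank, and 0.0478 by Mir692-3, Eif3b, Tmem92, Mad2l1bp, Ttll6, Mif4gd, Ube2v1 and Pparg. Pparg, a nuclear receptor gene, stood at 4.90 TPM in control (n = 41) and 8.13 TPM in low protein 2-cell embryos (n = 39) and was close to 0 later. Mif4gd differed by -0.46 at the 4-cell and 0.80 at the morula stage, Tmem92 by -0.77 and 0.61, Ttll6 by -0.64 and 0.60, Mad2l1bp by -0.32 at the 2-cell and 0.48 at the morula stage, and Ube2v1 by -0.53 and 0.28. In 6 of 100 groupings as many genes or more passed, with 105 genes in the highest other one, so chance cannot be excluded for the 14, and the high count of that other grouping points to structure among the samples. With sire means as replicates only Mir692-3 passed (limma adjusted p = 0.0333), listed at 0 TPM in 2-cell and 4-cell embryos and at 44.05 and 10.9 TPM in control and low protein blastocysts, where 2 sire pairs are complete. So a diet effect that changes with stage stays open.

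For the diet comparisons at unadjusted p under 0.05, groupings reached the real count of 717 genes in 14 of 100 at the 2-cell stage (highest other 1325), 511 in 36 of 100 at the 4-cell stage (highest other 1193) and 322 in 60 of 100 at the blastocyst stage (highest other 812), and chance cannot be excluded there. At the morula stage 3 of 100 reached 996, with 1945 in the highest other grouping, so chance among single embryos is a less likely source of that number. The groupings reassign embryos within plate and not sires, so they cannot exclude chance differences between sires. Groupings with nearly 2 times the real count also point to structure among the samples. For the stage changes only the real grouping, 1 of 100, reached 7882, 4021 and 2693 genes, with 984, 2823 and 751 in the highest other one, and chance can be excluded.

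Low protein morulae had 996 genes at unadjusted p under 0.05, 90.8% of them higher, and such a lean could come from scaling, from embryos with few genes, or from their place along the course. After quantile normalization the share of genes was 10.2% instead of 10.4%, so the number stayed. The genes changed in part, as 616 of the 979 were among the 996. No groupings of embryos were drawn after that normalization, so the number kept cannot exclude scaling as its source. Of the 979 genes 56.1% were higher. That step moves the median difference over all genes from 0.118 to -0.00597. The share higher then falls whatever made the lean, so it cannot tell the source of the direction. With genes detected as a covariate 759 genes (7.95%) reached that p and 65.5% were higher, which cannot tell whether poor embryos carry the direction. With the course scores as covariates 4.7% of genes (449) reached that p, 243 of them among the 996, but the scores come from the same embryos. Whether scaling, the diet, the pace of development or embryo quality makes the lean stays open.

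Ribosomal protein genes were lower in low protein 2-cell embryos by -0.34, a pattern that 1 sire pair or an earlier place within the 2-cell stage could produce. With a sire pair left out at least 77.4% of the difference remained, which argues against a single pair. With the course score as covariate 25.6% remained (-0.09 ± 0.07 SE), and 32.9% for nucleolar genes. The score left out both lists, but it comes from the same embryos, and both lists rise along that course. Their differences would then shrink whatever lowered them, so this cannot tell whether the embryos were earlier. A delay caused by the father's diet, or by the time of collection, stays open, and embryos timed from fertilization would test it.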

How the results depend on the processing

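The alternatives that use sire, oocyte donor, Rn45s, 7000 genes, plate 6 blastocysts and added covariates were chosen after seeing the data. Among the alternatives to the main results 224 stayed as reported, 25 moved, 2 were stronger and 1 reversed, and the cause was not tested. The 2-cell diet comparison gave 1 gene, Enpp1, with a pseudocount of 0.1, without plate 3, without sire pair FVB7-23 (the same embryos as plate 3 there) and without FVB9-9, against 0 as reported. At the morula stage the number of genes was 1 after quantile normalization (Pmm1), 1 with run means (H2-D1), 6 with array weights, 3 without embryos under 5000 genes, 4 without those under 7000, 2 without plate 3, 1 without plate 4, 2 with the oocyte donor in place of plate, 2 without FVB7-23, 4 without FVB9-9 and 3 with genes detected as covariate. The range was 0 to 6. Only 1 embryo, a morula, had fewer than 5000 genes, so leaving such embryos out changed nothing at the other stages. The blastocyst comparison gave 31 genes with sire as a correlated block, where the estimated correlation was -0.04, and 0 to 31 over all alternatives. Leaving out single late blastocysts gave 0 to 869 genes, and single 8-cell embryos 0. The interaction gave 0 genes with a pseudocount of 0.1, 2 after quantile normalization, 3 without plate covariate, 7 without Rn45s, 7 without plate 6 blastocysts, 2 without sire pair FVB8-11 and 1 with sire means, within a range of 0 to 15. With a pseudocount of 0.1 the embryo to embryo variability at the 4-cell stage differed by 0.121 (range over alternatives -0.0299 to 0.121) and the embryo to embryo variability at the morula stage by -0.188 (range -0.188 to -0.00779). The two-sided permutation gave an adjusted p of 0.0309 for each, against up to 0.234 and 0.875 over the alternatives. At the blastocyst stage the spread around the mean of stage and diet reversed to 0.0522 (adjusted p = 0.0158), where the low protein blastocysts of 1 plate have no control beside them. The number of genes changing ranged from 7875 to 8495 for the first stage step, 3509 to 5283 for the second and 2373 to 2879 for the third.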

Other observations

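Late blastocysts, compared by values alone because plate and stage coincide, were mixed in genes of the primitive endoderm. Gata6 stood at 11.2 ± 6.48 TPM (SD, n = 14) in control blastocysts and 42.9 ± 18.4 TPM (n = 2) in control late blastocysts, and at 20.6 ± 13.04 (n = 22) and 74.2 ± 27.1 TPM (n = 3) with low protein sires. Lrp2 went from 33.8 ± 9.08 to 66.9 ± 34.7 TPM and from 30.1 ± 12.04 to 127 ± 26.96 TPM in the same groups, while the epiblast gene Nanog went from 415 ± 147 to 192 ± 13.7 TPM and from 312 ± 137 to 190.4 ± 90.9 TPM. Pdgfra went from 5.25 ± 2.95 to 2.09 ± 2.95 TPM and from 4.59 ± 2.91 to 1.10 ± 1.19 TPM, and Lamb1 from 18.2 ± 11.6 to 6.70 ± 5.39 TPM and from 19.2 ± 6.83 to 5.98 ± 5.48 TPM. Sox17 and Gata4 were listed at 0 in all late blastocysts.

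Amhr2, a receptor known from granulosa cells, stood at 20.3 ± 35.2 TPM (SD, n = 41) at the 2-cell, 184 ± 48.4 TPM (n = 42) at the 4-cell and 23.1 ± 16.9 TPM (n = 38) at the morula stage in control embryos, and it was detected in 42 of 42 control 4-cell embryos. The granulosa marker Cyp19a1 stood at 6.09 ± 5.13 TPM at the 2-cell stage and 0.0362 ± 0.164 TPM at the 4-cell stage. Protamine Prm2, a sperm transcript, stood at 5.04 ± 6.32 TPM (n = 41) with control and 4.98 ± 6.04 TPM (n = 39) with low protein sires at the 2-cell stage. Xist was present in 17 of 42 control and 26 of 40 low protein 4-cell embryos (two-sided Fisher exact test, p = 0.0298, adjusted p = 0.179) and Y-linked transcripts in 23 of 42 and 11 of 40 (p = 0.0147, adjusted p = 0.176), so the balance of sexes did not pass. In blastocysts the counts ran the other way without passing, at 12 of 14 and 12 of 22 for Xist (p = 0.0756, adjusted p = 0.302) and 3 of 14 and 11 of 22 for Y-linked transcripts (p = 0.160, adjusted p = 0.480).

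The test of oocyte donors was written down before it was run, but the wording of its label was changed after the result was seen, because a count reached by many reassignments does not exclude a donor effect. At the 4-cell stage the test held 74 embryos of 6 sire pairs and 14 oocyte donors, with donors compared within sire pair. In it 1961 genes differed between donors at unadjusted p under 0.05. That count was reached by 1 of 100 reassignments of donors, the real one, with 1538 in the highest other. Of the 1961 genes 63 passed adjustment, led by Mzt2, Zfand5, Zfp553, Aar2 and Sap30, against 46 in the highest other reassignment. At the 2-cell stage 23 of 100 reached the real count of 1041 (highest other 1756) and at the morula stage 43 of 100 reached 1058 (highest other 3469). After adjustment 132 genes passed in morulae, but 32 of 100 reassignments reached that number and the highest other gave 2132, so a donor effect stays open at both stages. Oocyte quality may differ between donors at the 4-cell stage, but the time of collection may differ between donors as well, so a test would need several donors per sire collected at the same hour.

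As a hypothesis, embryos of low protein sires may lag slightly along the developmental course, since the course score of 2-cell embryos toward the 4-cell stage and that of morulae toward the blastocyst were lower without passing. With the scores as covariates 25.6% of the ribosomal difference was left, and 4.7% of tested morula genes reached an unadjusted p under 0.05. The ribosomal genes rise along the same course, so the difference left cannot tell a lag from another cause. Against a lag, the score from the 4-cell stage differed by 0.04 in morulae, and both 4-cell scores differed by -0.01. In blastocysts the score from the morula differed by 0.22 ± 0.25 (SE) with plate as covariate. The group means there ran the other way, 3.12 in control and 2.65 in low protein embryos, so that score cannot decide. The scores and the patterns come from the same embryos, so this is not an independent test. Time-lapse records of cleavage, with several sires per diet and embryos collected at fixed hours, would test it.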
